A study of Mus musculus with 24 samples.

How the data were processed

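The series holds 24 samples from 6 male C57BL/6 mice at postnatal day 0.5, 3 wild type and 3 with a knockout of Ftsj1, per the labels. Per the labels' protocols, brains and livers were dissected and snap-frozen, and lysates were used for ribosome profiling, or total RNA was taken and selected for poly(A). Ribosome-contained mRNA is the RNA protected by ribosomes in such a lysate, sequenced as footprints. The processing tools named are Bowtie2, HISAT2 and HTSeq with the mouse build mm10, per the submitters' processing notes, and their versions and settings are not given in the sources used here.

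The brain mRNA values are deposited as raw read counts per RefSeq transcript in 12 libraries, with no scaling by the authors, as their whole numbers and differing column totals show. The codon values are deposited as raw counts of footprints whose ribosomal A site, the place where a codon is decoded, lay on each of the 64 codons, in 6 brain and 6 liver libraries. How the A site was placed within a footprint is not given in the sources used here. The fits had been planned for normalised codon values or for counts, and because the codon values were counts the planned count model was used.

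Of 106519 transcripts, 86027 matched a gene by accession without its version in the RefSeq annotation of GRCm38.p6, and these held 98.7% of all reads. Counts were summed per gene, which left 53291 genes and unmatched transcripts. Reads lay mostly on genes with 1 annotated transcript: protein-coding genes with 1 transcript held 85.9% of all reads. Of the 8993 such genes 41.3% had at least 60 reads over the 6 total mRNA libraries, against 6.82% of genes with 6 or more transcripts. Levels of a gene with several transcripts are therefore uncertain, and comparisons of the same gene between genotypes rest on the same counted part. The 13 mitochondrially encoded protein transcripts held 93 reads in all and were not compared.

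Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 as a quasi-likelihood model with TMM scaling on only the libraries compared. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and all 61 sense codons were kept. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes or codons tested, and an adjusted p under 0.05 was called. Changes are log2 ratios with their standard error (SE), and levels are read counts scaled to library size (CPM) or percent of sense-codon counts as mean ± SD of 3 mice. The comparisons were knockout against wild type in brain total mRNA, in brain ribosome-contained mRNA, in their ratio (translation efficiency, the interaction of genotype and library kind), and in the A-site codons of brain and of liver. The others were the interaction of genotype and tissue for codons, ribosome-contained against total mRNA in wild-type brain, and brain against liver codons in wild type. The share of both phenylalanine codons was compared by an exact two-sided permutation test on mean log2 values.

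For the correlation with codon content, coding sequences were taken from GENCODE vM21 for 21538 genes, and its significance came from exact regroupings of the mice. A set of 34 gene lists and 6 codon lists was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, for lists with at least 5 genes or 2 codons tested. The genes named were set by a rule: Ftsj1, the 10 genes with the smallest adjusted p called in each direction, every gene called in both kinds of library, and up to 4 members of each list reported, the 2 with the smallest p and the 2 most abundant. With fewer than 5 calls the 5 genes with the smallest p in each direction were named as not passing. For codons the rule named every codon of the lists and up to 10 called codons, or with fewer than 3 calls the 3 with the smallest p in each direction. The groups, comparisons, lists, naming rule and 77 alternatives were fixed before the data were examined, and 28 alternatives and 4 gene lists were added afterwards. Alternatives covered DESeq2 1.42.0, other scalings and filters, a block for the replicate number, and leaving out each library. Alternatives for a pseudocount did not apply to counts and were not run.

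The total and ribosome-contained libraries of a number come from 1 mouse, as do the brain and liver samples, per the source names in the labels. In the gene data the deviations from group means of the same mouse's libraries correlated at 0.107 to 0.206 in wild type and 0.120 to 0.191 in knockout, against a highest value of -0.00237 and -0.00176 between different mice. In the codon data the brain and liver of 1 mouse correlated at -0.134 to -0.0622 in wild type and -0.195 to -0.104 in knockout.

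Total mRNA libraries held 2605126 to 3409910 reads, ribosome-contained brain libraries 331235 to 481804, and codon libraries 11350 to 26414 counts. The median 95% half-width of a gene's log2 change was 0.35 in total mRNA, 0.46 in ribosome-contained mRNA and 0.82 in translation efficiency, and that of a codon was 0.18 in brain and 0.21 in liver. A count of 0 was given a floor of 3 reads. Unlike those half-widths, floors and exact counting intervals cover counting error only and not the spread between mice. Reads without molecular identifiers are not independent molecules, so even the counting error may be larger than given. Each step was tested on simulated counts with 200 genes or 12 codons changed. Recovery of a 1.5-fold and a 2-fold change was 48.4% and 78.1% of genes in total mRNA, 49.3% and 79.0% in ribosome-contained mRNA, and 13.8% and 34.3% in translation efficiency. For codons a 1.25-fold change was recovered in 5 of 6 codons in brain, 4 of 6 in liver and 2 of 6 in the interaction, and 4 of 16 calls between wild-type brain and liver were false. Over 100 further draws, added after that result was seen, recovery of a 1.25-fold change was 71.8% in brain, 65.5% in liver, 40.2% in the interaction and 73.8% between wild-type tissues, and the mean share of false calls was 2.30%, 4.85%, 2.77% and 4.95%. With fewer genes or codons changed the Benjamini-Hochberg adjustment is stricter, so these rates do not give the recovery of a change in 1 codon or a few genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No deposited column was left unused, and liver mRNA levels per gene were not analysed here.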

Results

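Ftsj1 encodes a methyltransferase that adds a 2'-O-methyl group to the anticodon loop of a few tRNAs, among them those for phenylalanine, tryptophan and leucine. The samples fall into 8 groups of 3 mice: total mRNA and ribosome-contained mRNA of wild-type and knockout brain, sequenced per transcript, and A-site codons of ribosome-contained mRNA in wild-type and knockout brain and liver. Brain total mRNA had 2605126 to 3409910 reads per library and ribosome-contained mRNA 331235 to 481804, and the codon libraries had 11350 to 26414 counts. Across 3413 genes, the log2 CPM of libraries of 1 kind correlated at a Pearson r of 0.967 to 0.994 and of different kinds at 0.594 to 0.618. Ftsj1 itself had 0 reads in all 12 brain libraries of both genotypes on its 2 transcripts, and since reads shared between transcripts seem not to have been counted, this sets no limit on its level. The wild-type brains also had 0 reads, so the targeted gene checked no label.

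The knockout effect on mRNA levels was measured in brain total mRNA, where 8 genes were lower and 1 was higher. Cdhr1, a cadherin-related protein of photoreceptors and of olfactory bulb projection neurons, fell from 159 ± 18.9 to 42.4 ± 16.8 CPM (log2 -1.90, SE 0.18, n = 3 and 3, edgeR adjusted p = 0.00021). Tfap2e, a transcription factor of those same projection neurons, fell from 6.75 ± 1.60 to 1.14 ± 0.180 CPM (log2 -2.52, SE 0.44, edgeR adjusted p = 0.0321). Foxd3, a neural crest transcription factor, fell from 10.8 ± 1.28 to 1.14 ± 0.706 CPM (log2 -3.19, SE 0.42, edgeR adjusted p = 0.00566). Eef1a2, the form of translation elongation factor 1A made in neurons and muscle, rose from 570.3 ± 41.3 to 737 ± 13.5 CPM (log2 0.37, SE 0.06, edgeR adjusted p = 0.0315).

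The other genes that fell were Mafa, a transcription factor best known from pancreatic beta cells (log2 -2.13, SE 0.34), and Frzb, a secreted Wnt antagonist (log2 -1.43, SE 0.25). Apold1, an early-response gene of endothelium, fell by 0.85 on the log2 scale (SE 0.14), and the growth factor gene Gdf10 fell by 0.53 (SE 0.09). Igfbp5, which binds insulin-like growth factors, fell from 724 ± 31.5 to 547 ± 35.9 CPM (log2 -0.41, SE 0.06, edgeR adjusted p = 0.0246). For each of these genes all 3 knockout values lay on 1 side of all 3 wild-type values. In GRCm38.p6, Cdhr1 lies on chromosome 14 at 37077849 to 37098347, Foxd3 on chromosome 4 at 99656299 to 99658671 and Tfap2e on chromosome 4 at 126716003 to 126736269. Igfbp5 lies on chromosome 1 at 72858065 to 72874865 and Eef1a2 on chromosome 2 at 181141758 to 181157015.

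In all, 9 of 6561 genes were called by edgeR, 1 higher and 8 lower, and 297 had an unadjusted p under 0.05 where 328 would be expected with no effect. The 3 values per group did not overlap for 674 genes (10.3%, where chance gives 10%). Cdhr1 was called whichever library was left out. Leaving out wild-type replicate 2 left 4 calls, wild-type replicate 3 left 3, knockout replicate 1 left 2 and knockout replicate 2 left 1. Eef1a2 was not called without wild-type replicate 2 or 3 or any of the 3 knockout replicates, Igfbp5 without wild-type replicate 3 or knockout replicate 1 or 2, and Foxd3 without knockout replicate 2. Tfap2e was not called by DESeq2 or with any of the 6 libraries left out. Mafa, Frzb and Gdf10 were not called without wild-type replicate 2 or 3 or knockout replicate 1 or 2, Gdf10 also without knockout replicate 3, and Apold1 without wild-type replicate 1 or 3 or any knockout replicate. Slc38a5, the neighbour of Ftsj1 on the X chromosome, did not pass (log2 -0.63, SE 0.15, edgeR adjusted p = 0.315) but was the 1 gene of that list lower when adjusted over the list alone.

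**Figure D1:**
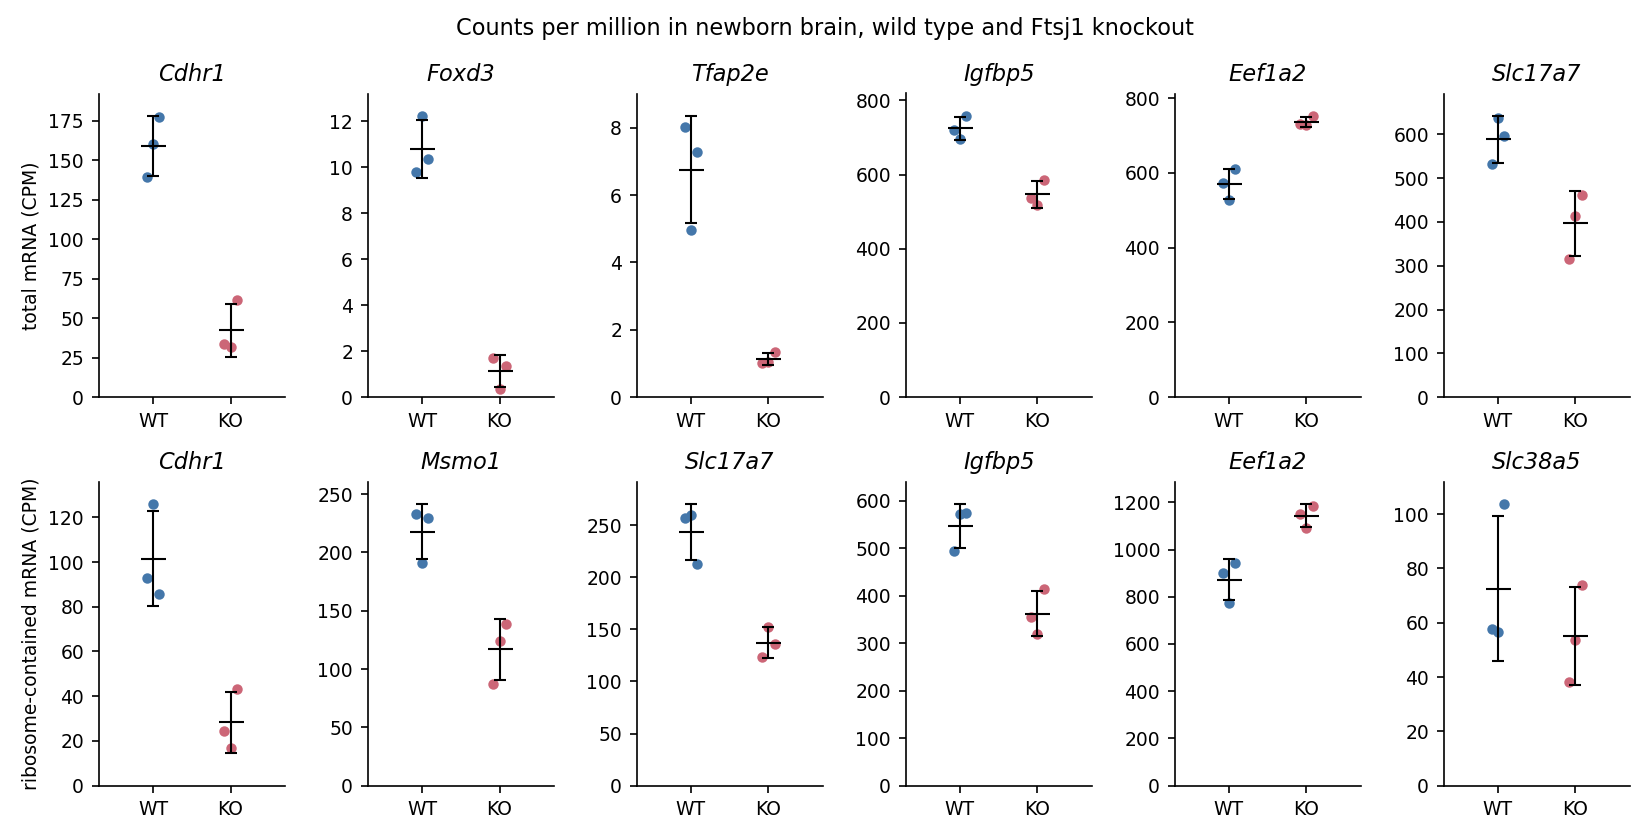
Normalised read counts (CPM) on the vertical axis for each mouse of the wild-type and knockout groups, with mean and SD, for 6 genes in total mRNA (upper panels) and 6 in ribosome-contained mRNA (lower panels) of newborn brain. Cdhr1 fell from 159 to 42.4 CPM in total mRNA and from 102 to 28.3 CPM in ribosome-contained mRNA, with no overlap between genotypes.

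Among groups of genes in total mRNA, the cytosolic ribosomal proteins were slightly higher in the knockout, with 50 of 57 genes positive and a median log2 of 0.10 (camera adjusted p = 6.06e-07; adjusted p = 0.231 with an estimated correlation). The members with the smallest p were Rpl23 (log2 0.31, SE 0.10) and Rpl7 (log2 0.26, SE 0.09), and the abundant Rpl4 had 0.05. Nuclear oxidative phosphorylation genes, which encode the respiratory chain, were higher by a median of 0.06 in 29 of 37 genes (adjusted p = 0.0409; adjusted p = 0.825 with an estimated correlation), with Sdhc at 0.78, Cox6c at 0.18, Atp5a1 at 0.03 and Atp5b at 0.00. Genes of inhibitory neurons were lower in 10 of 12 (median -0.15, adjusted p = 0.0409; adjusted p = 0.825 with an estimated correlation), with Dlx6os1 at -0.31, Npy at -0.17, Slc32a1 at -0.09 and Gad2 at 0.05. Presynaptic genes were lower in 13 of 17 (median -0.07, adjusted p = 0.0455; adjusted p = 0.825 with an estimated correlation), with Slc17a7 at -0.57, Pclo at -0.20, Vamp2 at -0.10 and Cplx2 at -0.07.

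Adjusted over the list alone, 0 genes of the ribosomal protein, oxidative phosphorylation and inhibitory neuron lists passed in edgeR, and 1 presynaptic gene, Slc17a7, was lower. Of 34 lists 31 had at least 5 tested genes and these 4 were called, 2 higher and 2 lower, and 0 were called with an estimated correlation or by fry. The ribosomal proteins were called whichever library was left out. Oxidative phosphorylation was not called without wild-type replicate 2 (adjusted p = 0.241), knockout replicate 2 (0.201) or knockout replicate 3 (0.0833). Inhibitory neurons were not called without wild-type replicate 2 (0.122), wild-type replicate 3 (0.0622), knockout replicate 1 (0.193) or knockout replicate 3 (0.267). Presynaptic genes were not called without wild-type replicate 1 (0.193), wild-type replicate 3 (0.0622), knockout replicate 1 (0.517) or knockout replicate 3 (0.167).

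The ribosome-contained mRNA of the same brains shows which messages ribosomes were translating, and there 4 genes were lower in the knockout. Cdhr1 fell from 102 ± 21.3 to 28.3 ± 13.5 CPM (log2 -1.87, SE 0.30, n = 3 and 3, edgeR adjusted p = 0.000346). Slc17a7, the vesicular glutamate transporter of excitatory neurons, fell from 243 ± 26.7 to 137 ± 14.6 CPM (log2 -0.84, SE 0.17, edgeR adjusted p = 0.0135). Msmo1, a sterol oxidase of cholesterol synthesis, fell from 218 ± 23.4 to 117 ± 26.5 CPM (log2 -0.92, SE 0.19, edgeR adjusted p = 0.0135). Igfbp5 fell from 546 ± 45.5 to 362 ± 47.8 CPM (log2 -0.60, SE 0.13, edgeR adjusted p = 0.0135). In all 4 genes every knockout value lay below every wild-type value, and Msmo1 lies on chromosome 8 at 64718123 to 64733578 and Slc17a7 on chromosome 7 at 45163921 to 45176139.

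These were 4 of 3485 genes tested in ribosome-contained mRNA by edgeR, with 149 at an unadjusted p under 0.05 where 174.2 would be expected with no effect, and DESeq2 called only Cdhr1. Eef1a2 was higher without passing (log2 0.39, SE 0.10, edgeR adjusted p = 0.180), as were Mtarc2 (log2 0.82), Chrna3 (log2 1.16), Lonrf1 (log2 0.70) and A430033K04Rik (log2 0.73), and Vaultrc5 was lower without passing (log2 -0.55, adjusted p = 0.376). Igfbp5 was not called without wild-type replicate 2 or 3 or knockout replicate 1 or 2, Msmo1 without wild-type replicate 3 or knockout replicate 1, and Slc17a7 without wild-type replicate 2 or knockout replicate 1. The count was 8 without wild-type replicate 1 or knockout replicate 3, 2 without wild-type replicate 2 or 3, and 1 without knockout replicate 1. Genes of excitatory neurons were lower as a group in 4 of 6 (median -0.28, camera adjusted p = 0.0174; adjusted p = 0.635 with an estimated correlation), with Slc17a7 at -0.84, Fezf2 at -0.50, Neurod6 at -0.09 and Neurod2 at 0.03, and 1 lower adjusted over the list alone. This was the 1 list called among 25, and it was not called without wild-type replicate 1 (adjusted p = 0.15), knockout replicate 1 (0.156) or knockout replicate 2 (0.0815).

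Cdhr1 and Igfbp5 were called in both kinds of library, 2 genes where 0.00582 would be shared by independent lists of 5 and 4 among the 3435 genes tested in both (Fisher's exact p = 1.02e-05). All 5 genes called in total mRNA and tested in both had the same sign in ribosome-contained mRNA. Gdf10 was at -0.49 (SE 0.18) and Frzb at -1.15 (SE 0.47) on the log2 scale there. Across these genes, which are not independent replicates, the knockout changes in both kinds correlated with a Pearson r of 0.258 and a Spearman rho of 0.226. Both kinds of library come from the same mice, so differences between mice alone can give shared calls, and the Fisher p does not test an effect of genotype.

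Translation efficiency, the ratio of ribosome-contained to total mRNA, tests whether loss of the methyltransferase altered how well single messages were translated. No gene passed: 0 of 6035 in edgeR, with 195 at an unadjusted p under 0.05 where 301.8 would be expected with no effect, and 0 in DESeq2. The genes with the smallest p, each at an edgeR adjusted p of 1.0, were Zfp709 (log2 1.26, SE 0.40), Lonrf1 (log2 0.76, SE 0.24), Pcyox1l (log2 1.82, SE 0.61) and Kxd1 (log2 1.03, SE 0.35) among those higher. Tbc1d32 was the other, with 12 ribosome-contained reads in knockout and 1 in wild type, a ratio of 14.1 with a 95% exact counting interval of 2.08 to 600.5. Among those lower were Ldb1 (log2 -2.08, SE 0.49), Msmo1 (log2 -0.67, SE 0.21), B3galt6 (log2 -0.75, SE 0.23) and an unnamed RefSeq transcript (log2 -0.97). Islr2 was the other, with 0 reads in knockout ribosome-contained mRNA and 7.44 CPM in wild type against a floor of 7.92 CPM, so no fold is given. The median 95% half-width of 0.82 is not adjusted over the genes tested, so it is not the limit of detection. In simulated counts a 2-fold change was recovered in 34.3% of genes and a 4-fold change in 65.6%. Changes larger than that half-width therefore stay open as well, and 0 of 31 gene lists were called.

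The translation efficiency change was set against the share of the phenylalanine codons TTT and TTC in each coding sequence, since ribosomes that dwell longer on those codons would raise the ribosome-contained reads of genes rich in them. Across 5159 genes, which are not independent replicates, Spearman's rho was -0.00283, and 6 of the 10 regroupings of the mice gave a value as large, the highest other being 0.0118. Over the 61 sense codons rho ran from -0.0268 to 0.0293. TTT and TTC together made up only 2.96% of sense-codon counts in wild-type brain, and the median 95% half-width of a gene's change was 0.82. The rho that slower decoding would give was not worked out, so a value near 0 does not argue against it.

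The wild-type brain libraries show which messages carried more or fewer ribosome-protected reads for their total mRNA. Replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, stood highest, with 13 of 13 called higher and a median log2 of 6.98 (range 5.21 to 8.56). Total mRNA was selected for the poly(A) tail that these mRNAs lack, so their ratios do not show that they were translated more. H1f2 had 25.9 ± 1.99 CPM in poly(A)-selected total mRNA and 2416 ± 157 CPM in ribosome-contained mRNA (log2 6.53, SE 0.11, edgeR adjusted p = 9.11e-27), and H4c8 had 4.22 ± 0.969 and 1205 ± 57.5 CPM (log2 8.16, SE 0.14). Genes of meningeal fibroblasts were higher by a median of 1.28, with the collagen gene Col1a1 at 1.92 (SE 0.09), Igfbp2 at 1.57 and Col1a2 at 1.34. Cytosolic ribosomal protein genes were lower by a median of -1.55, with Rps15a at -5.27 (SE 0.25), Rplp0 at -2.16 (SE 0.11) and Rpl4 at -0.69 (SE 0.08).

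Nuclear oxidative phosphorylation genes were higher by a median of 0.83, with Ndufa4 at 1.33 (SE 0.11) and Atp5b at 0.88 (SE 0.07). Cytosolic heat shock genes were higher by 0.99 with the chaperones Hsp90aa1 at 1.60 and Hspa8 at 1.02, and genes of the unfolded protein response by 0.55 with Hsp90b1 at 1.20, Pdia3 at 0.93 and Calr at 0.91. Microglia genes were higher by 0.88, with Mrc1 at 1.53 and Pf4 at 1.64, and cell cycle genes by 0.72, with the ribonucleotide reductase subunits Rrm1 at 1.11 and Rrm2 at 0.88. Presynaptic genes were lower by a median of -0.81, with Cplx2 at -4.81 and Vamp2 at -0.59 but Syp at 0.61, and Bsn, with 0 ribosome-contained reads, at least 39.1-fold lower against a floor of 3 reads per library.

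**Figure D2:**
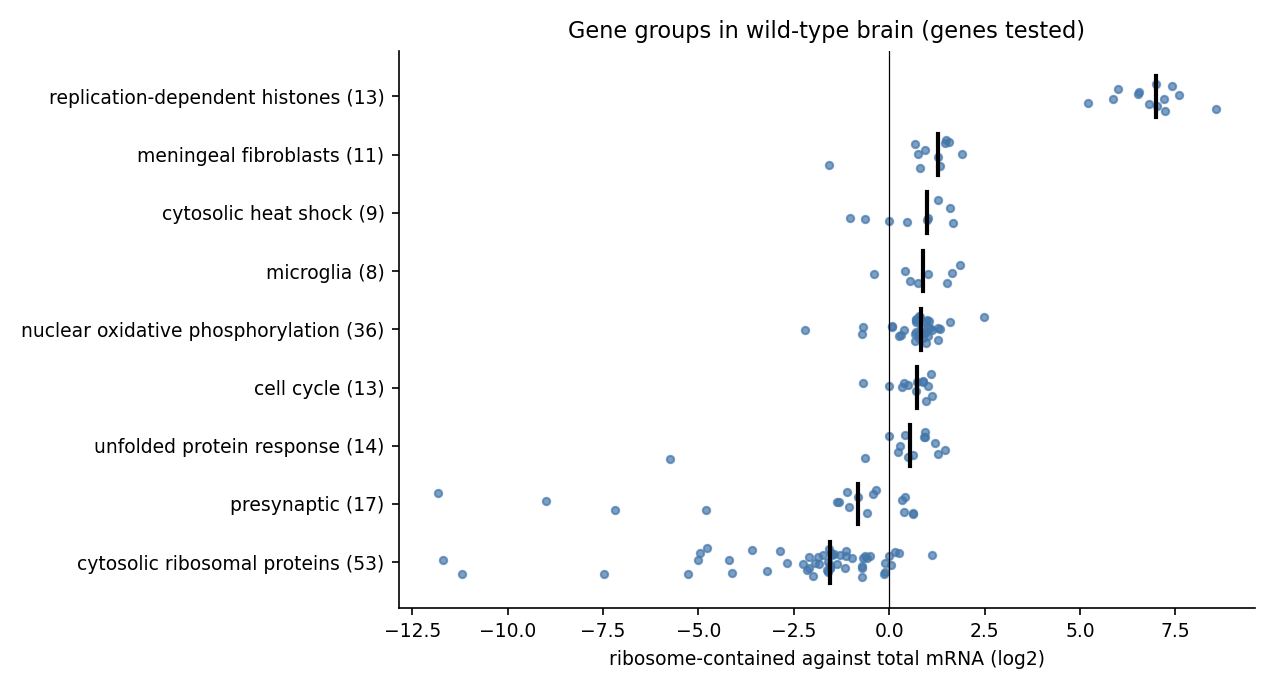
Log2 ratio of ribosome-contained to total mRNA in wild-type brain on 1 axis for groups of genes on the other, with 1 point per gene and a bar at the median, and genes without ribosome-contained reads drawn at their fitted value. Histone genes lay between 5.21 and 8.56, and ribosomal protein genes had a median of -1.55.

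These 9 lists were called by camera among 30 tested, and none with an estimated correlation: adjusted p = 9.28e-28 for histones (0.114 estimated), 4.50e-09 for oxidative phosphorylation (0.299), 2.00e-08 for ribosomal proteins (0.114), 0.000148 for meningeal fibroblasts (0.114), 0.0374 for heat shock (0.299), 0.0367 for presynaptic genes (0.437), 0.0407 for the unfolded protein response (0.485), 0.0407 for the cell cycle (0.565) and 0.0480 for microglia (0.520). With the mouse as a block the presynaptic list was not called (adjusted p = 0.0663). Adjusted over the list alone, 13 histone, 10 meningeal, 30 oxidative phosphorylation, 6 heat shock, 6 microglia, 8 cell cycle and 8 unfolded protein response genes were higher, and 44 ribosomal protein and 11 presynaptic genes lower, with 0 to 3 genes per list in the other direction. Setting the 3 ribosomal protein genes and 2 presynaptic genes without ribosome-contained reads to their floor left medians of -1.55 and -0.81. Microglia were not called without total replicate 2 (adjusted p = 0.0654) or ribosome-contained replicate 1 (0.122), 2 (0.174) or 3 (0.174), and the cell cycle without ribosome-contained replicate 1 (0.101), 2 (0.195) or 3 (0.0970). The unfolded protein response was not called without total replicate 1 (0.0549) or 2 (0.0654) or ribosome-contained replicate 1 (0.0930) or 3 (0.0649), and heat shock without ribosome-contained replicate 3 (0.0561), which left 5 lists.

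Over all genes 3544 of 5549 were called by edgeR, 1530 higher and 2014 lower, and the median gene was at -0.11. The other 8 genes highest by adjusted p were the histone genes H4c4, H2ac18, H1f4, H1f3, H2bc18, H4c17, H3c7 and H1f1, between 6.01 and 7.87. Adcy1, an adenylyl cyclase, fell from 4983 ± 407 CPM in total to 348 ± 37.6 CPM in ribosome-contained mRNA (log2 -3.84, SE 0.10), with Rnf130 at -5.99, Map6 at -8.12, Lrrc8b at -5.81, Negr1 at -4.12 and Cplx2 at -4.81. Zwint had 8170 reads in total and 2 in ribosome-contained mRNA, a ratio of 613 with a 95% exact counting interval of 169.7 to 5064, and Mir6236 had 11430 CPM in total mRNA and 0 ribosome-contained reads, at least 1710-fold lower. Of these low genes only Adcy1 and the microRNA gene Mir6236 have 1 annotated transcript, and levels of the others are uncertain. The ratio of Mir6236 does not describe a coding message. With genes of 1 transcript alone, an alternative chosen after seeing the data, 2222 of 3504 were called, histones kept a median of 6.93 and ribosomal proteins of -1.60, while presynaptic genes had a median of -0.07 and were not called (6 genes, adjusted p = 0.705). Heat shock (median 0.97, adjusted p = 0.0909), the unfolded protein response (0.57, adjusted p = 0.0909), the cell cycle (0.67, adjusted p = 0.255) and microglia (0.60, adjusted p = 0.255) were not called with these genes either.

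The codon at the A site is the codon being decoded, so slower decoding by a tRNA lacking its methyl group would raise the share of its codon. In brain the phenylalanine codon TTT went from 1.21 ± 0.107% of sense-codon counts in wild type to 1.45 ± 0.0414% in knockout (log2 0.27, SE 0.08, n = 3 and 3) without passing (edgeR adjusted p = 0.121), though all 3 knockout values lay above all 3 wild-type values, as for 9 of 61 codons in either direction (14.8%, where chance gives 10%). The other codons of tRNAs that the enzyme methylates did not pass either: TTC for phenylalanine at 0.07 (SE 0.10), TGG for tryptophan at -0.09 (SE 0.07) and TTG for leucine at 0.00 (SE 0.09). The asparagine codon AAT went from 1.51 ± 0.0876% to 1.17 ± 0.110% (log2 -0.37, SE 0.09, edgeR adjusted p = 0.0519) and the tyrosine codon TAT from 1.01 ± 0.0559% to 0.804 ± 0.00920% (log2 -0.34, SE 0.08, edgeR adjusted p = 0.0519).

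edgeR called 0 of 61 codons in brain, with 7 at an unadjusted p under 0.05 where 3.05 would be expected with no effect, and DESeq2 called 0. The newer edgeR quasi-likelihood method, chosen after seeing the data, called AAT and TAT (adjusted p = 0.0388 for both), limma called TAT on centred log ratios (0.0412) and with trend (0.0308), and edgeR with the replicate number as a block called AAT (0.00742). Next by p came the serine codon AGC (log2 0.25), the leucine codon CTG (log2 0.14) and the lysine codon AAA (log2 -0.19). AAT passed without wild-type replicate 2 (edgeR adjusted p = 0.0461). TTT passed when adjusted over the list of phenylalanine codons alone (edgeR adjusted p = 0.0142), while that list did not pass camera (adjusted p = 0.148). The remaining listed codons did not pass, with TTA at -0.13, CGT at 0.14, CGC at -0.23, CGA at -0.20, CGG at 0.03, CAA at -0.16 and CAG at -0.02.

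**Figure D3:**
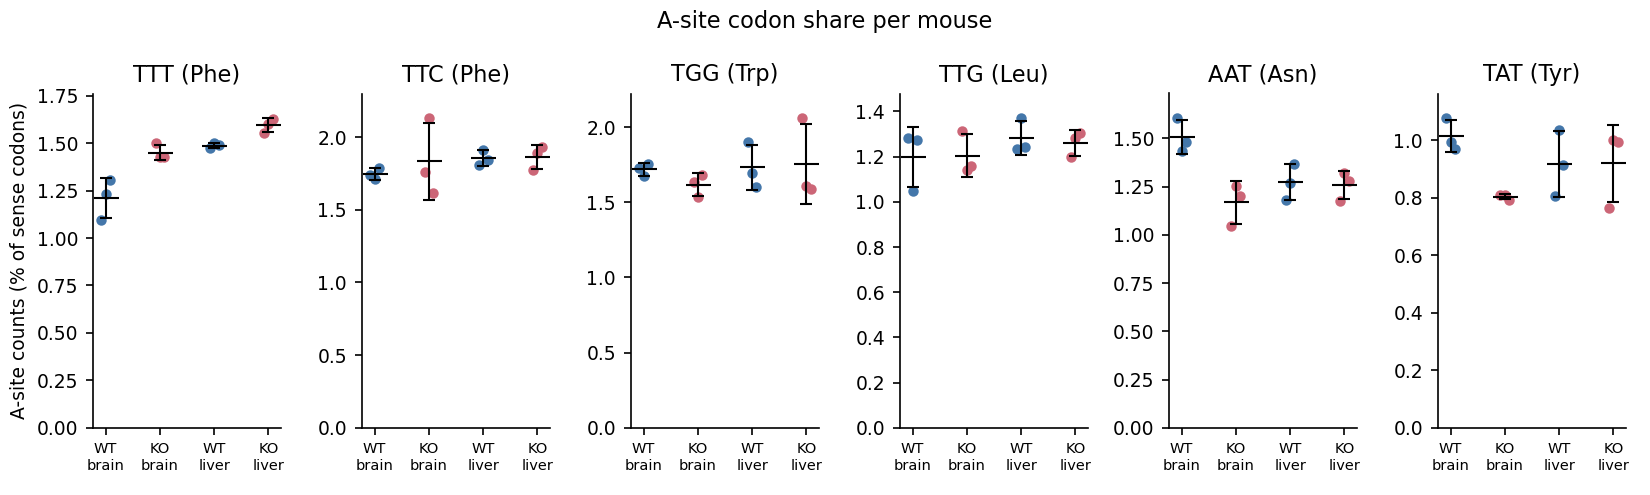
Share of sense-codon counts (percent, vertical axis) of 6 codons for each mouse in wild-type and knockout brain and liver, with mean and SD. In brain TTT went from 1.21% to 1.45%, AAT from 1.51% to 1.17% and TAT from 1.01% to 0.804%, none passing adjustment with the edgeR method used for all comparisons, while its newer quasi-likelihood method called AAT and TAT.

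In liver of the same mice the codons of these tRNAs did not pass either, with TTT at 1.49 ± 0.0144% in wild type and 1.59 ± 0.0368% in knockout (log2 0.11, SE 0.07, n = 3 and 3, with no overlap between genotypes, as for 5 of 61 codons), AAT at -0.02 (SE 0.09) and TAT at 0.00 (SE 0.12). edgeR called 0 of 61 codons, with 0 at an unadjusted p under 0.05, and DESeq2 called 0. TTC was at 0.01, TGG at 0.02, TTG at -0.02, TTA at -0.02, CGT at 0.02, CGC at -0.04, CGA at -0.04, CGG at 0.18, CAA at -0.19 and CAG at 0.09, and AGG (0.18), GAT (-0.12) and GCC (-0.08) were next by p. Knockout liver replicate 1 differed from the other knockout livers by a chi-square per degree of freedom of 2.10 and 2.53, against 1.44 between those. Both phenylalanine codons together made up 2.96 ± 0.130% in wild-type and 3.29 ± 0.262% in knockout brain (log2 0.16, exact two-sided permutation p = 0.20) and 3.34 ± 0.0672% and 3.46 ± 0.119% in liver (log2 0.05, exact permutation p = 0.20). With 3 mice against 3 the smallest p of that exact test is 0.1.

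The knockout effect was compared between brain and liver by the interaction, in which AAT (log2 -0.35, SE 0.13), GAT (log2 0.22, SE 0.10) and TAT (log2 -0.34, SE 0.16) had the smallest p in edgeR. None passed adjustment (smallest edgeR adjusted p = 0.789), giving 0 of 61 codons with 3 at an unadjusted p under 0.05, and DESeq2 called 0. TTT was at 0.16 (SE 0.12), TTC at 0.06 (SE 0.12), TGG at -0.11 (SE 0.14) and TTG at 0.02 (SE 0.14). AGC (0.24), ATC (0.18) and ACT (-0.26) were next by p.

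**Figure D4:**
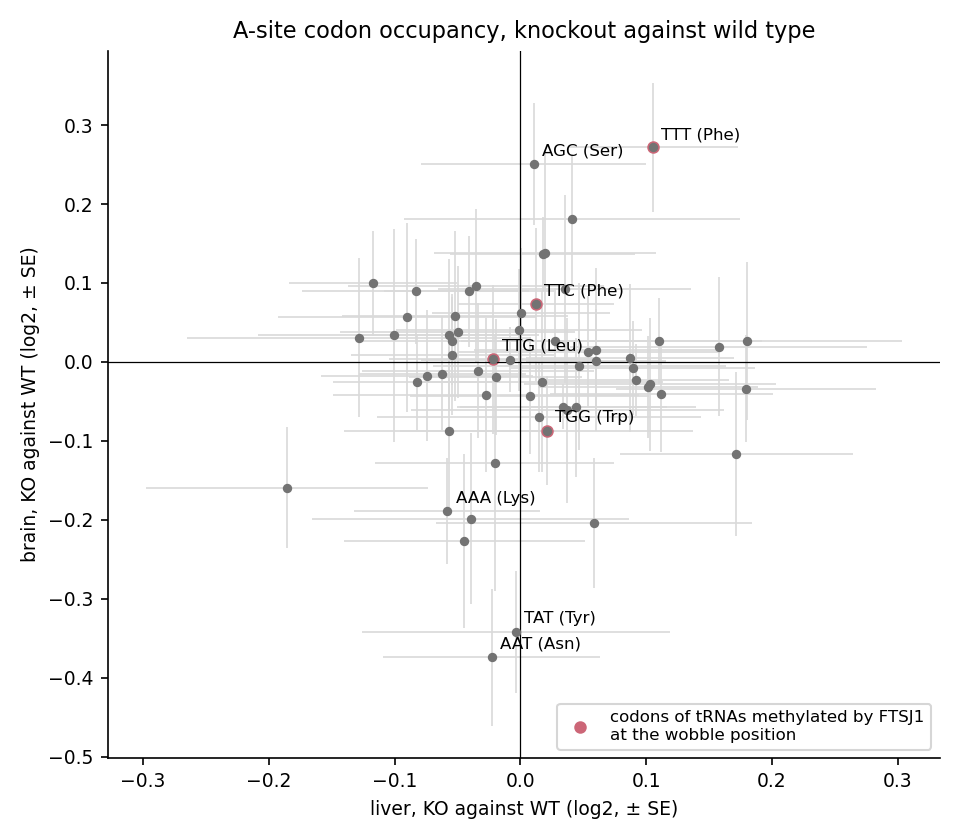
Log2 change of each of 61 codons in knockout against wild type, brain on the vertical and liver on the horizontal axis, with SE as bars and the codons of tRNAs methylated by FTSJ1 ringed in red. TTT lay at 0.27 in brain and 0.11 in liver, and AAT at -0.37 and -0.02.

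Wild-type brain and liver differed in the codons at the A site, with the arginine codons CGG and CGA more frequent in brain. Such shares also depend on the codons of the mRNAs that each tissue translates. That was not corrected for, so the differences below do not show a difference in decoding speed. CGG made up 1.48 ± 0.169% in brain and 0.960 ± 0.0861% in liver (log2 0.60, SE 0.10, n = 3 and 3, edgeR adjusted p = 0.00089), and CGA 0.949 ± 0.0508% and 0.622 ± 0.0708% (log2 0.61, SE 0.11). The cysteine codon TGC was less frequent in brain, at 1.20 ± 0.0695% against 1.64 ± 0.176% (log2 -0.49, SE 0.10, edgeR adjusted p = 0.00113). The phenylalanine codon TTT was also less frequent in brain (log2 -0.34, SE 0.09, edgeR adjusted p = 0.00414), and without brain replicate 1 the call ended at log2 -0.23 (adjusted p = 0.0518). In all 22 of 61 codons were called, 9 higher in brain and 13 lower, and 18 by DESeq2. This balance moved with the setting: 12 were higher and 12 lower when scaled to the sense-codon total, and 10 higher and 8 lower without brain replicate 1.

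The other codons higher in brain were GCG (0.44), GGG (0.37), CCA (0.31), AGG (0.29), CAG (0.26), ATG (0.19) and GAG (0.19), and those lower were TCT (-0.43), TGT (-0.43), ACC (-0.33), GCC (-0.31), AAG (-0.31), GCT (-0.29), CTG (-0.26), GAT (-0.24), TCC (-0.21), GGA (-0.21) and GTG (-0.20). With the mouse as a block ATG (adjusted p = 0.0567) and TCC (0.0961) were not called, and DESeq2 did not call these, GGA or GTG. Leaving out 1 library left 17 to 23 codons: TCC was not called without any of the 6 libraries (adjusted p from 0.0527 to 0.316), ATG without brain replicate 2 (0.118) or 3 (0.129) or liver replicate 1 (0.0996) or 2 (0.155), GGA without brain replicate 1 (0.187) or 2 (0.0542) or liver replicate 1 (0.114) or 3 (0.128), and GTG without brain replicate 1 (0.124) or 2 (0.0527) or liver replicate 1 (0.0706) or 2 (0.0936). TGT was not called without brain replicate 1 (0.0911) or liver replicate 2 (0.0558) or 3 (0.0627), AGG without brain replicate 3 (0.0565) and GAT without brain replicate 2 (0.0504), each with its direction kept. TTC (-0.13), TGG (-0.03), TTG (-0.14), TTA (0.08), CGT (0.04), CGC (0.19) and CAA (-0.05) did not pass. As a group the 4 arginine CGN codons were higher in brain (median 0.40, camera adjusted p = 0.0480; adjusted p = 0.522 with an estimated correlation), with 2 passing adjusted over the list alone. The group was not called without brain replicate 1 (adjusted p = 0.0762) or 2 (0.15) or liver replicate 1 (0.0986), 2 (0.127) or 3 (0.203).

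**Figure D5:**
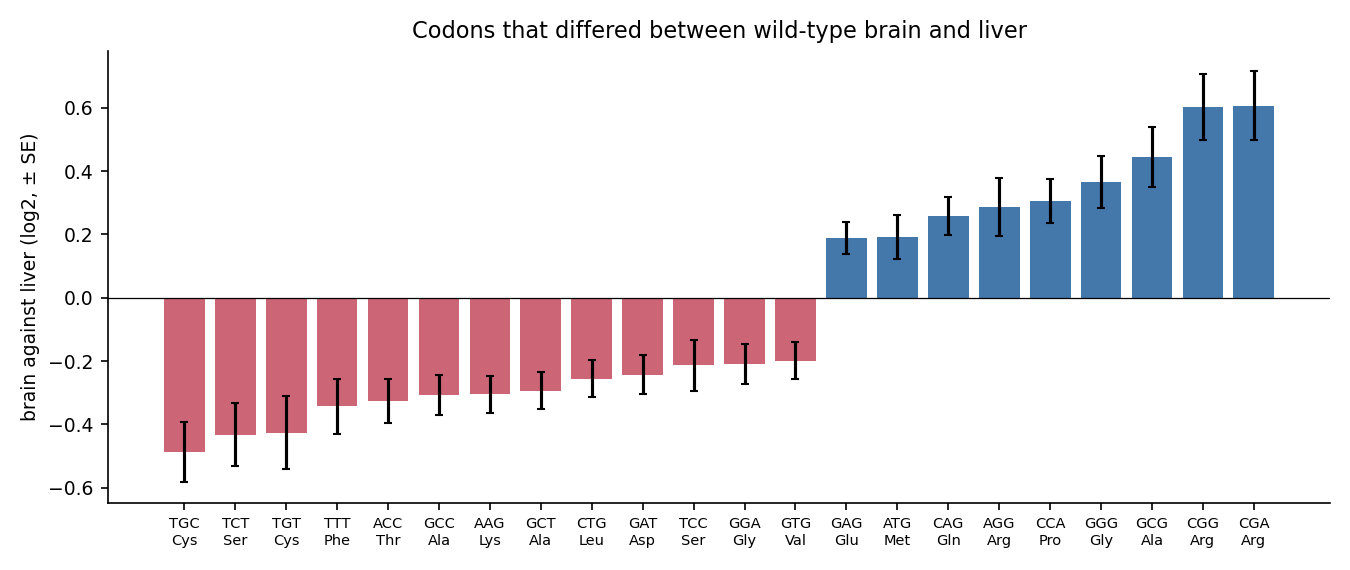
Log2 ratio of the A-site share in wild-type brain to that in wild-type liver for the 22 codons called, as bars with SE. CGA at 0.61 and CGG at 0.60 were highest, and TGC at -0.49 was lowest.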

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

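Of the alternatives below, the newer edgeR quasi-likelihood method, DESeq2 on codons, genes with 1 transcript and leaving out libraries from the list tests and the codon-content correlation were chosen after seeing the data. Against the 9 genes called in total mRNA, 17 were called with no filter and 1 with a mean count of at least 50, which removed low genes such as Foxd3 from the test; why abundant genes such as Igfbp5 and Eef1a2 were not called with it was not tested. DESeq2 called 1 gene in ribosome-contained mRNA against 4. An estimated correlation left 0 lists in total mRNA, 0 in ribosome-contained mRNA, 0 in wild-type ribosome-contained against total mRNA and 0 among codon lists of brain against liver, where sense-total scaling also left 0. fry, which does not compare a list with other genes, called 0, 0 and 23 of the gene lists. With genes of 1 transcript 2222 were called against 3544, since fewer were tested. In brain codons, centred log ratios gave 1 call (TAT), limma with trend 1 (TAT) and the newer edgeR method 2 (AAT, TAT), against 0, and the cause was not tested. Wild-type and knockout mice share only replicate numbers: the replicate block gave 12 genes in total mRNA, 5 in ribosome-contained mRNA and 1 codon (AAT) in brain, and same-numbered libraries correlated at 0.132, -0.155 and 0.245 in total mRNA, 0.202, -0.0461 and 0.199 in ribosome-contained mRNA, 0.0971, -0.0718 and 0.0720 in brain codons and 0.123, 0.0800 and 0.202 in liver codons. The mouse as a block gave 3586 genes and 20 codons in the paired wild-type comparisons, and beyond the presynaptic list, ATG and TCC it changed no other call of a named gene, list or codon there. Leaving out 1 library gave 1 to 11 genes and 1 to 7 lists in total mRNA (7 without wild-type replicate 1, 2 without knockout replicate 1, 1 without knockout replicate 3), 1 to 8 genes and 0 to 1 list in ribosome-contained mRNA, 5 to 10 lists in wild-type ribosome-contained against total mRNA, 0 to 1 brain codon, 0 to 1 codon list between tissues, and a codon-content rho of -0.0137 to -0.00232. A group left with 2 libraries keeps a test because the spread is pooled. Hepatocyte genes, not called with all libraries in total mRNA, were lower without wild-type replicate 1 (adjusted p = 6.00e-07) and higher without wild-type replicate 3 (4.47e-07). Of 1498 values for 115 named genes and codons, 1402 kept direction and side of the threshold, 52 lost and 8 gained a call, and 36 changed sign, none of them for a called gene or codon. DESeq2 put liver TTC at -0.0128, TGG at -0.00406 and CGT at -0.00333, and sense-total scaling put TGG of brain against liver at 0.00397. With 1 library left out, log2 changes ran in brain from -0.051 to 0.15 for TTC, -0.080 to 0.070 for TTG, -0.044 to 0.13 for CGG and -0.045 to 0.030 for CAG. In liver they ran from -0.012 to 0.031 for TTC, -0.12 to 0.12 for TGG, -0.049 to 0.025 for TTG, -0.12 to 0.053 for TTA, -0.038 to 0.070 for CGT, -0.084 to 0.027 for CGC and -0.15 to 0.094 for CGA. For the interaction they ran from -0.049 to 0.18 for TTC, -0.22 to 0.031 for TGG, -0.10 to 0.11 for TTG, -0.26 to 0.10 for TTA, -0.41 to 0.042 for CGA, -0.29 to 0.027 for CGG and -0.081 to 0.11 for CAA. For brain against liver they ran from -0.052 to 0.063 for TGG, -0.00305 to 0.20 for TTA, -0.014 to 0.17 for CGT and -0.048 to 0.011 for CAA. At the depth of the codon libraries the median 95% half-width was 0.18 in brain and 0.21 in liver on the log2 scale, so smaller changes stay open. This half-width is not adjusted over the codons tested, so larger changes stay open as well. In brain TTT at 0.27 (SE 0.08) lay beyond it and was not called.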

Other observations

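The olfactory and cholesterol gene lists, the forebrain, region score and splits tests, the test across libraries and the test on other codons of methylated tRNAs were chosen only after the results they follow were seen. Genes of cholesterol synthesis were lower in knockout brain in both kinds of library. Their change in translation efficiency did not pass (median -0.08, camera adjusted p = 0.370; adjusted p = 0.736 with an estimated correlation), so the kinds of library were not shown to differ. In ribosome-contained mRNA 11 of 12 were lower (median -0.23, camera adjusted p = 5.01e-08; adjusted p = 0.0294 with an estimated correlation), with the sterol oxidase gene Msmo1 at -0.92 (SE 0.19), the isomerase gene Idi1 at -0.51 (SE 0.17) and the squalene epoxidase gene Sqle at -0.33 (SE 0.11), these 3 passing when adjusted over the list alone. In total mRNA 10 of 14 were lower (median -0.16, camera adjusted p = 3.36e-05; adjusted p = 0.145 with an estimated correlation and 0.156 by fry), with Idi1 at -0.37 (SE 0.10) and Insig1 at -0.32 (SE 0.09) passing when adjusted over the list alone. Without Msmo1, Idi1 and Sqle, which had prompted the list, 8 of 9 genes were lower in ribosome-contained mRNA with a median of -0.166 (camera p = 0.00201, 0.0383 with an estimated correlation) and 7 of 11 in total mRNA with a median of -0.152 (camera p = 0.00408, 0.19 with an estimated correlation). The mean score of the list did not overlap between genotypes in ribosome-contained mRNA, but in total mRNA it did (wild type -0.0034, 0.0236 and 0.184, knockout -0.211, -0.0506 and 0.0575), and there it parted wild-type mouse 1 and knockout mice 1 and 2 from the others, the split described below. Within each genotype the ribosome-contained score followed that split too. Wild-type mouse 1 (0.0681) lay below mice 2 and 3 (0.138 and 0.217), and knockout mice 1 and 2 (-0.249 and -0.119) below mouse 3 (-0.0550). A lower expression of the sterol pathway as a whole may therefore reach beyond the genes that drew attention, as a hypothesis found and tested on the same 6 mice. For both kinds of library that structure of the samples stays open.

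Cdhr1, Tfap2e, Foxd3 and Frzb, all lower in knockout brain, are known from projection neurons or ensheathing glia of the olfactory bulb. For Cdhr1 and Frzb an artefact of the total mRNA libraries is argued against, since they were at -1.87 (SE 0.30) and -1.15 (SE 0.47) in ribosome-contained mRNA (median -1.51), while for Tfap2e and Foxd3 it cannot be told apart, since they had only 36 ribosome-contained reads (12 in wild type and 1 in knockout, and 20 and 3). Less olfactory bulb in the knockout samples or animals cannot be told apart from lower expression within its cells. Lists written without the genes called each had a negative median in total mRNA, but not all of them did in ribosome-contained mRNA. In total mRNA ensheathing glia genes were lower in 5 of 5 (median -0.222, camera adjusted p = 0.000306; adjusted p = 0.116 with an estimated correlation) and bulb interneuron genes in 8 of 10 (median -0.17, adjusted p = 0.0118; 0.116 estimated). Mitral and tufted neuron genes were lower in 4 of 5 without passing (median -0.05, camera adjusted p = 0.0765). The mean scores of the glia list and of the mitral and tufted list did not overlap between genotypes, and that of the interneuron list did. Adjusted over its list alone in edgeR, the glia gene Erbb3 was lower (log2 -1.56, adjusted p = 0.0172). So were the mitral and tufted gene Tbx21 (log2 -1.67, adjusted p = 0.0185) and the interneuron gene Tshz1 (log2 -0.24, adjusted p = 0.0352). In ribosome-contained mRNA ensheathing glia genes were lower in 3 of 3 (median -0.21), but interneuron genes in only 4 of 7 (median -0.15, camera adjusted p = 0.515). There 2 of 3 mitral and tufted genes were higher (median 0.33), with Lhx1 at 1.18 (SE 0.46, edgeR adjusted p = 0.0394 over the list alone). These 3 genes were too few for camera, and Tbx21 and Erbb3 were not tested in ribosome-contained mRNA. A different share of forebrain cannot be told apart from these, since the forebrain score differed by -0.0962 in total mRNA (wild type 0.05 ± 0.20, knockout -0.05 ± 0.03, 10 genes; list median -0.08, camera adjusted p = 0.0295) and by -0.203 in ribosome-contained mRNA (0.10 ± 0.13 and -0.10 ± 0.15, 7 genes; list median -0.21, adjusted p = 0.00258), and the midbrain and hindbrain score by 0.516 in total mRNA (-0.26 ± 0.71 and 0.26 ± 0.80, 4 genes). The lower Slc17a7 and excitatory neuron genes are open to that explanation as well. The inhibitory neuron list shares Gad2, Dlx6 and other genes with the bulb interneuron list, so its lower values are not separate evidence.

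In brain codons AAT and TAT were lower and TTT higher in knockout without passing with the edgeR method used for all comparisons or DESeq2, though AAT or TAT passed with 4 other methods and AAT without wild-type replicate 2. A change in which mRNAs were translated is argued against for the genes counted. Their ribosome-contained counts and coding sequences predicted a change of -0.00111 for AAT and between -0.0094 and 0.0074 for every codon, from 93.9% of the counted reads. Predicted and observed changes correlated with a Spearman rho of -0.0496 across codons, while the prediction followed the wild-type codon shares with a rho of 0.933. Genes with several transcripts hold few of the counted reads, so a change among those genes stays open. Whether the gene and codon libraries came from the same preparations is not given, so a difference found only in the codon libraries stays open. A rise shared by TTC, TGG and TTG as large as that of TTT (log2 0.27) is argued against too, since these 3 codons of methylated tRNAs had a mean change of -0.00357 (SE 0.0506). Smaller slowing, slowing of a single codon among them and codons of other methylated tRNAs stay open, with TTC alone at 0.07 (SE 0.10). Slower decoding of TTT alone may remain. TTT passed when adjusted over the phenylalanine codons alone (edgeR adjusted p = 0.0142) but not over all 61 codons (edgeR adjusted p = 0.121). Both phenylalanine codons together gave an exact permutation p of 0.2, so chance in 3 mice against 3 is not excluded. How the A site was placed is not given, so a shift in its placement stays open as well.

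Very low ratios of ribosome-contained to total mRNA in wild-type brain may come in part from the counting. A log2 ratio under -3 was found for 100 of 3502 genes with 1 transcript (2.86%) and for 347 of 1464 genes with several (23.7%), 8.30 times the share (Fisher's exact p = 4.12e-109). The ratio also rose with the coding share of the transcript across 3357 genes, which are not independent replicates (Spearman rho 0.331), from a median of -0.57 in the 25% of genes with the lowest share to 0.38 in the 25% with the highest, as reads of total mRNA on untranslated regions would give. Ribosomal protein genes with 1 transcript kept a median of -1.60, so the counting of several transcripts does not account for theirs.

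Each set of 6 libraries can be split into groups of 3 in only 10 ways, too few for a share under 0.05. In total mRNA 2 of 10 splits gave as many genes as the real 9 (highest other 69) and 5 gave as many lists as the real 4 (highest other 5). In ribosome-contained mRNA 2 gave as many genes as the real 4 (highest other 33) and 4 as many lists as the real 1 (highest other 1). The split of wild-type mouse 1 and knockout mice 1 and 2 against the others gave both the 69 and the 33, which points to a structure of the samples. Brains with different shares of forebrain and of midbrain or hindbrain could give it: a score of forebrain against midbrain and hindbrain genes correlated between the kinds of library over the 6 mice (Pearson r = 0.873, exact permutation p = 0.0181; Spearman rho 0.943, exact permutation p = 0.0167; r = 0.649 without the 2 mice farthest from the median, so it rests partly on those). The score in total mRNA was 5.08, 4.49 and 5.11 in those 3 mice and 6.17, 5.29 and 5.62 in the others, with as few as 25 midbrain and hindbrain reads in a ribosome-contained library.

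Where the real count is 0 every split gives as many, so these tell nothing: 10 of 10 for genes (highest other 0) and lists (highest other 1) in translation efficiency, and 10 of 10 for codons in brain, in liver and in the interaction (highest other 0 each) and codon lists (highest other 1 in brain, 0 in liver and 0 in the interaction). By unadjusted p under 0.05, the real grouping had 7 codons in brain (highest other 6), 0 in liver (highest other 6), 3 in the interaction (highest other 8) and 195 genes in translation efficiency (highest other 297). For wild-type ribosome-contained against total mRNA 1 split, the real one, gave 3544 genes (highest other 0) and 1 gave 9 lists (highest other 7). For wild-type brain against liver 1 split gave 22 codons (highest other 0) and 3 gave as many codon lists as the real 1 (highest other 1). In these wild-type comparisons every other split mixed kinds of library or tissues within a group, which widens the spread. The 0 calls of those splits therefore say little about chance.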
